A study of Homo sapiens with 524 samples.

How the data were processed

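RNA from 59 lines of the NCI-60 panel was hybridised to Affymetrix human arrays, 1 per cell line, dose and time, 524 in all. Per the labels' protocols, drug in DMSO (0.25% final) was added to cells plated a day before, total RNA was isolated with a column kit and labelled with biotin. The deposited values are log2 signal intensities, 1 per probe set and array, between 2.54 and 14.3. How the authors summarised and normalized them is not given in the sources used here. The range was checked against the 16-bit scanner limit (16 on the log2 scale), and the array medians lay between 4.96 and 5.28. The values were used as deposited, with no further scaling in the main results.

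The table holds 22277 probe sets. By the platform annotation 19070 have 1 gene symbol, 1043 several and 2164 none, and 19058 of the first group matched the RefSeq table by gene identifier, with 0 symbols changed. A gene was represented by the probe set with the highest mean over all arrays among those with 1 symbol, which gave 11963 genes (4310 with more than 1 probe set), and no filter on low signal was applied. Genes linked to the Y chromosome and XIST were left out of all named results. Probe sets with several symbols or none were tested apart and not named.

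Groups were taken from the dose and time in the labels, tissue from the tissue label, and the cell line was the replicate. For each gene the within-line difference between 2 arrays was tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3), so that the line acts as a block, and p was adjusted by Benjamini-Hochberg over all genes (threshold 0.05). A change of 0.5 or more was counted separately. The pairing comes from the design, since arrays of 1 line share its name, and it was checked on the data: 521 of 524 arrays correlated best with another array of their own line. Responses at different times were compared as a difference of differences, and the 2 doses directly, without the vehicle arrays. Tissues were compared on the within-line response to 10000 nM in 1 limma fit of the 8 tissues with at least 3 lines (Prostate, with 2, was left out), by an F test and by contrasts of each tissue with the mean of the other 7. Mutation status was not used.

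Before the data were examined, 33 gene lists (555 distinct genes, 479 measured), the comparisons, the alternatives and the rule for named genes were fixed. The lists covered ERK pathway output, immediate early genes, the ATF4 integrated stress response, aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones, cholesterol and fatty acid synthesis, LXR, NRF2, p53, NF-kappaB, YAP and AHR targets, heat shock genes, metallothioneins, iron handling, hypoxia, glycolysis, the TXNIP family, oxidative phosphorylation, DNA replication, mitosis, ribosome biogenesis, ribosomal proteins, lysosome and autophagy, the BCL2 family, kinases that sorafenib binds, interferon genes, pigment, epithelial, mesenchymal and haematopoietic markers, and reference genes. Each was tested with camera in limma (preset correlation 0.01), with an estimated correlation and with fry beside it, adjusted over the lists of a comparison; the TXNIP family had 1 measured gene and no list test. ATF3 stands in 2 lists, as do EGR1 and several others. The rule named, for 10000 nM against vehicle at each time, the 8 largest rises and 8 largest falls among genes past the threshold with the same sign in at least 75% of lines, and up to 2 members of each list, of which those with small changes are not all printed. For other comparisons it named the 3 largest rises and falls, and for the F test 5 genes. ATF3 and other genes named in 1 comparison were given in others where they bear on it.

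Per-line summaries were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and drawn with matplotlib 3.10.9. The number of genes changed by at least 1 was compared between doses by sign flips, and relations between lists by Pearson and Spearman correlations with permutation p (100000 resamples, two-sided). Array quality was read from the 3 prime and 5 prime control probe sets of ACTB and GAPDH, the array median and the interquartile range.

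The scripts were tested on simulated data built from the real spread. In the within-line fit at 10000 nM, 64, 42 and 24% of genes changed by 0.1 were recovered at 2, 6 and 24 h, 98, 96 and 88% of those changed by 0.25, and 100% at 0.5, with 3 or 4 unchanged genes called. Only 50 of 11963 genes were changed at each size, far fewer than passed in the real comparisons at this dose. The gene means in this fit were also drawn independently of each other, so recovery and false calls in the real data may differ. The Leukemia contrast at 6 h recovered 85% at 0.5 and 99% at 1, and the F test at 6 h 56% and 98%. At 24 h recovery was lower, 32% and 79% for the Leukemia contrast and 8% and 57% for the F test, so Leukemia differences of this size were often missed there. Changes were added only to the Leukemia lines, of which there were 4 at 24 h, so recovery for the larger tissues was not measured.

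The alternatives were no block, 1 fit of all arrays, other choices of probe set, a filter on mean signal, median centring, quantile normalization, a robust fit, an intensity trend, a sign-rank test, a threshold of 0.01, lines with all 9 arrays (52 lines), the panel without SNB-19 and NCI-ADR-RES, and lines or tissues left out in turn. Settings that leave out MOLT-4, HCT-116, SK-MEL-2, SK-MEL-5 or CCRF-CEM, or that add the ACTB covariate, were added after the data were seen, and so was the use of the setting without SNB-19 and NCI-ADR-RES for tissues. The vehicle profiles of NCI-ADR-RES and OVCAR-8 correlated at 0.966 and those of SNB-19 and U251 at 0.935, so these pairs are close, yet each line counts as a replicate in the main results. For each comparison 100 regroupings of the arrays were drawn, exchanging arrays within lines or tissue labels between lines.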

Results

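The series measured mRNA levels in 59 established human tumour cell lines of the NCI-60 panel exposed to sorafenib, an oral inhibitor of RAF kinases and of receptor tyrosine kinases such as the VEGF and PDGF receptors. Each line was sampled 2, 6 and 24 h after addition of 0, 5000 or 10000 nM drug in 0.25% DMSO, with 1 array per line, dose and time. The 524 arrays comprised 59 vehicle arrays at each time, 57, 57 and 59 arrays at 5000 nM, and 59, 58 and 57 arrays at 10000 nM (2, 6 and 24 h). The lines came from 9 tissues (6 Breast, 6 CNS, 7 Colon, 6 Leukemia, 9 Lung, 8 Melanoma, 7 Ovarian, 2 Prostate and 8 Renal). Unless another comparison is named, a change below is the log2 value of a treated array minus that of the vehicle array of the same line and time. It is given as mean ± SD over lines. The number of arrays limits the precision, and 11963 genes were tested.

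The comparison at 2 h asked which genes respond first. At 10000 nM, transcripts induced by growth factor signalling fell within 2 h (n = 59 lines). Of 21 measured targets of the RAF-MEK-ERK cascade, 12 fell and 0 rose (adjusted over the list alone, 15 fell and 1 rose; camera, adjusted p = 3.77e-12). They included EGR1, a growth factor induced transcription factor (-0.99 ± 1.56, lower in 47 lines), the early response gene IER3 (-0.99 ± 0.74, lower in 53 lines) and DUSP6, a phosphatase that acts on ERK (-0.87 ± 1.09). Among 16 immediate early genes 11 fell and 0 rose (12 and 0 adjusted over the list alone, adjusted p = 5.53e-16), with CCN2 at -0.63 ± 0.73 and ATF3 at -0.45 ± 0.81. MAFF fell in 58 of the lines (-0.84 ± 0.55), DUSP1 by -0.64 ± 0.69, the anti-apoptotic gene MCL1 by -0.34 ± 0.29 and TXNIP, which binds thioredoxin and restrains glucose uptake, by -0.86 ± 0.70. Of 6 aryl hydrocarbon receptor targets 2 fell and 0 rose, TIPARP (-0.73 ± 0.52) and CYP1B1 (-0.39 ± 0.45). The adjusted p of the list was 5.49e-04.

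A small set of stress genes rose at the same time. The largest rises were of DDIT4, an inhibitor of mTORC1 signalling (0.76 ± 1.15, higher in 45 of 59 lines), CHAC1, which degrades glutathione (0.56 ± 0.78), GADD45B (0.54 ± 0.45, higher in 55 lines) and DDIT3, which encodes the transcription factor CHOP (0.50 ± 0.63, higher in 52 lines). Smaller rises were those of ZKSCAN4 (0.30 ± 0.35), TSC22D3 (0.26 ± 0.39), the splicing kinase CLK4 (0.25 ± 0.31) and ZNF133 (0.25 ± 0.26). Of the 29 measured targets of ATF4, the transcription factor of the integrated stress response, 9 rose and 5 fell (11 and 7 adjusted over the list alone, adjusted p = 0.0470, and 0.443 with an estimated correlation). Without MOLT-4 and HCT-116, a setting added after the data were seen, the adjusted p of this list was 0.0593. Metal response genes rose in 6 of 8 cases, among them the zinc exporter SLC30A1 (0.26 ± 0.35, list adjusted p = 2.04e-06). The probe sets of MT1E, MT1F, MT1G, MT1H, MT1X and MT2A are marked as cross-hybridising, so these genes may share a signal. Small falls were already seen in 5 of 16 cholesterol synthesis genes, with INSIG1 at -0.30 ± 0.26 (adjusted p = 6.71e-06), in 15 of 28 mitotic genes (KIF23, -0.17 ± 0.18, list adjusted p = 3.08e-13), in 7 of 18 hypoxia genes against 2 that rose (VEGFA, -0.14 ± 0.34, list adjusted p = 0.0208, and 0.0543 with the ACTB 3 prime to 5 prime difference as covariate) and in 6 of 16 p53 targets against 1 that rose (CDKN1A, -0.26 ± 0.35, list adjusted p = 1.56e-04).

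In all, 1219 genes passed an adjusted p of 0.05 at 10000 nM and 2 h (527 higher and 692 lower), and 17 of them changed by 0.5 or more (4 higher and 13 lower). A single fit of all arrays with line by time as block gave 367. Of the 33 lists, 14 passed. Lists of ERK output (adjusted p = 0.00661 with an estimated correlation), immediate early genes, cholesterol synthesis, metallothioneins, hypoxia, p53, mitosis and AHR targets also passed with an estimated correlation. Adjusted over each list alone, the counts that differed were 5 higher for tRNA synthetases, 7 higher for metallothioneins, 2 higher and 9 lower for hypoxia, 19 lower for mitosis and 3 lower for AHR targets. They also differed for the BCL2 family (1 higher and 5 lower), NF-kappaB targets (1 and 6) and ribosomal proteins (0 and 0). The other 5 besides ATF4 were lost with an estimated correlation: tRNA synthetases (4 of 16 rose, adjusted p = 0.00145, then 0.0527), NRF2 targets (2 of 14 fell; 0.0424, then 0.0936), ribosomal proteins (1 of 20 rose; 0.0173, then 0.129), the BCL2 family (3 of 12 fell and 1 rose; 0.0424, then 0.0527) and NF-kappaB targets (5 of 18 fell and 1 rose; 0.00172, then 0.0936).

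The comparison at 6 h asked what followed. At 10000 nM and 6 h the integrated stress response rose in nearly all lines (n = 58). Of 29 ATF4 targets 26 rose and 1 fell (the same counts adjusted over the list alone), the list mean was 1.07 ± 0.39, and it lay above 0 in 57 lines (camera, adjusted p = 1.27e-33 and adjusted p = 6.24e-04 with an estimated correlation). The largest rises of all genes were those of CHAC1 (2.76 ± 1.09), DDIT4 (2.63 ± 1.35), DDIT3 (2.45 ± 0.79), ATF3 (2.44 ± 1.28) and TRIB3, a pseudokinase that restrains AKT (1.93 ± 0.88). The amino acid and gluconeogenic enzymes ASNS (1.48 ± 0.75) and PCK2 (1.51 ± 0.68), the cystine transporter SLC7A11 (1.13 ± 0.98) and the glucocorticoid induced gene TSC22D3 (1.66 ± 0.92) rose as well. Among aminoacyl-tRNA synthetases 10 of 16 rose and 1 fell (AARS1, 0.78 ± 0.33, list adjusted p = 3.09e-09, and 0.0222 with an estimated correlation).

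Genes of G1/S entry, sterol synthesis and ribosome assembly fell at 6 h. The cyclins CCNE2 (-0.95 ± 0.59) and CCNE1 (-0.78 ± 0.42) and the phosphatase CDC25A (-0.91 ± 0.46), which drive entry into S phase, were each lower in at least 56 lines. Of 29 DNA replication genes 18 fell and 4 rose (adjusted p = 8.06e-06 and adjusted p = 0.222 with an estimated correlation). Ribosome biogenesis genes fell in 15 of 17 cases with 0 higher (NOP16, -0.57 ± 0.32 and RRS1, -0.46 ± 0.32, list adjusted p = 5.09e-09, and 0.0433 with an estimated correlation). Of 16 cholesterol synthesis genes 12 fell (INSIG1, -0.96 ± 0.80 and IDI1, -0.48 ± 0.36, list adjusted p = 3.55e-05 and adjusted p = 0.114 with an estimated correlation). Other falls were those of the xenobiotic enzyme CYP1B1 (-1.05 ± 0.88), MAT2A, which makes S-adenosylmethionine (-0.91 ± 0.44), and ZFTA (-0.75 ± 0.49).

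All 8 metal response genes rose (MT1F, 0.90 ± 1.20 and MT1X, 0.88 ± 1.27, list adjusted p = 4.64e-05 and adjusted p = 0.222 with an estimated correlation). All of them but MT1M and SLC30A1 were read by probe sets marked as cross-hybridising, so the 8 rises are not separate signals. Endoplasmic reticulum genes rose in 8 of 17 cases and fell in 2 (HERPUD1, 1.17 ± 0.59 and XBP1, 1.06 ± 0.62, list adjusted p = 0.0146 and adjusted p = 0.482 with an estimated correlation). Lysosome and autophagy genes rose in 11 of 18 cases and fell in 2 (UVRAG, 0.37 ± 0.26, list adjusted p = 0.00334, then 0.110 with an estimated correlation). ERK output genes were still low, with 11 falls and 1 rise among 21 (IER3, -0.81 ± 0.99 and EGR1, -0.78 ± 1.71, list adjusted p = 0.0167, then 0.645 with an estimated correlation). Immediate early genes rose in 5 cases and fell in 4, KLF4 by 1.18 ± 0.85 (adjusted p = 0.682). Mitotic genes fell in 17 of 28 cases and rose in 1 (UBE2C, -0.22 ± 0.23, list adjusted p = 4.48e-05, then 0.434 with an estimated correlation). Of 20 ribosomal protein genes 4 rose (RPL3, 0.10 ± 0.09, list adjusted p = 0.0252, then 0.323 with an estimated correlation). GADD45A (1.29 ± 0.52), PMAIP1, which encodes NOXA (0.79 ± 0.74), TNFAIP3 (0.93 ± 0.87) and VEGFA (0.84 ± 0.74) rose within lists that did not pass as a whole.

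At 10000 nM and 6 h 4259 genes passed (2177 higher and 2082 lower), 151 of them with a change of 0.5 or more (96 higher and 55 lower). With each array centred on its own median the split became 1718 higher and 2578 lower. Of the 33 lists 11 passed with the preset correlation, 3 with an estimated one. Adjusted over each list alone, tRNA synthetases had 11 higher and 1 lower, cholesterol synthesis 2 and 12, DNA replication 4 and 19, mitosis 1 and 18, ERK output 1 and 12 and immediate early genes 5 and 5. At 2 h the mean and the median of the list differed in sign for iron handling, DNA replication and reference genes. At 6 h they differed in sign for immediate early genes, oxidative phosphorylation, p53 targets, the BCL2 family, YAP targets and reference genes, whose lists did not pass. SK-MEL-5 was the line in which the ATF4 list mean lay below 0 (-0.51).

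**Figure D1:**
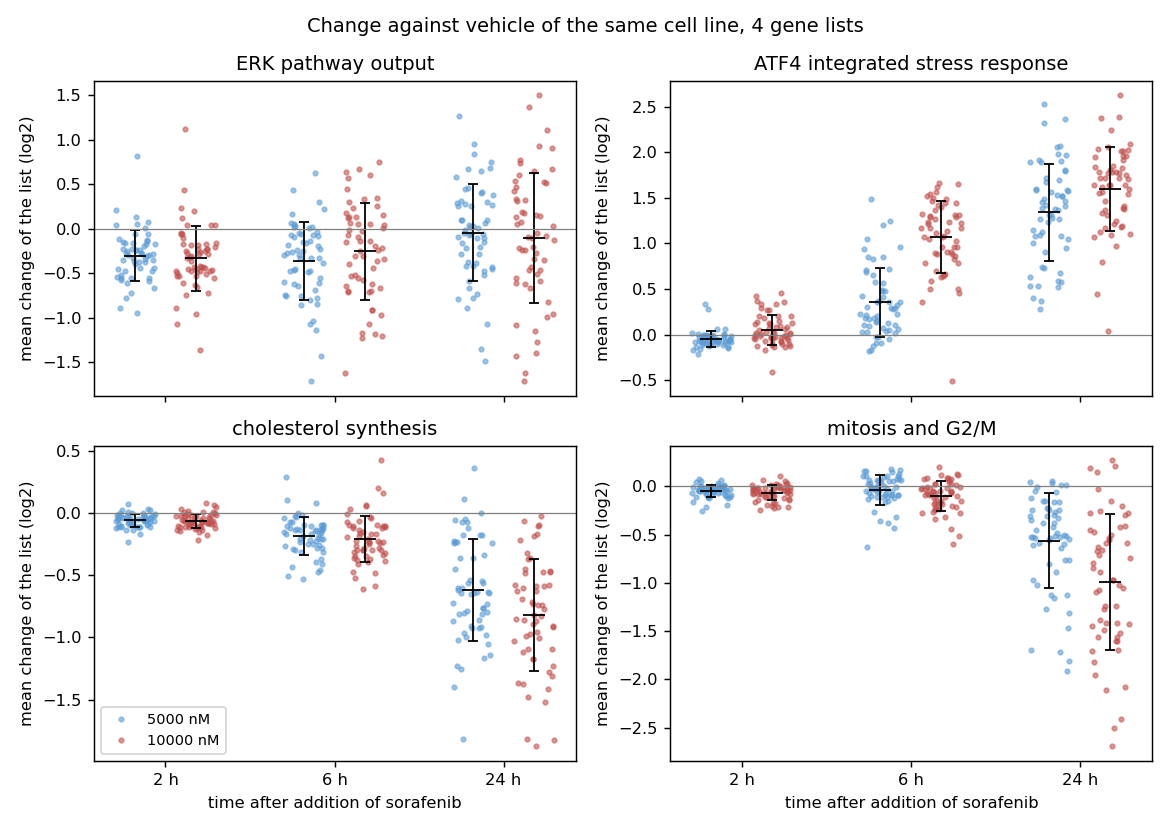
Mean change of 4 gene lists (log2, y axis) in each cell line (points) against the vehicle array of the same line and time, at 2, 6 and 24 h for 5000 and 10000 nM; horizontal marks and bars give mean and SD over lines. The ATF4 list mean at 10000 nM lies at 0.05, 1.07 and 1.60 at 2, 6 and 24 h, and the mitosis list mean at -0.06, -0.10 and -0.99.

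At 24 h the question was which program the lines had reached. Stress response genes stayed high at 10000 nM (n = 57 lines), and the ATF4 list mean was 1.60 ± 0.46 and above 0 in 57 of 57 lines. Of its 29 genes 26 rose and 0 fell (the same adjusted over the list alone; camera, adjusted p = 1.72e-21 and adjusted p = 0.00698 with an estimated correlation). The genes that rose most were ATF3 (3.17 ± 1.32), DDIT3 (3.08 ± 0.79), TRIB3 (3.06 ± 0.97), NIBAN1, a stress induced regulator of translation (2.97 ± 1.60), the lysosomal membrane gene LAMP3 (2.70 ± 2.06), NUPR1 (2.65 ± 1.66), ASNS (2.52 ± 0.96) and the secreted stress cytokine GDF15 (2.42 ± 1.83). tRNA synthetases rose in 11 of 16 cases and fell in 2, with WARS1 at 1.82 ± 0.58 and AARS1 at 1.43 ± 0.44 (adjusted p = 4.43e-08 and adjusted p = 0.1001 with an estimated correlation). Endoplasmic reticulum chaperone genes rose in 13 of 17 cases with 0 lower (DNAJB9, 1.82 ± 0.92 and HERPUD1, 1.57 ± 0.77, list adjusted p = 4.42e-06 and adjusted p = 0.275 with an estimated correlation).

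Cell cycle genes fell together at 24 h. All 29 DNA replication genes and all 28 mitotic genes were lower, also when adjusted over each list alone and with the sign of the list mean kept under median centring and quantile normalization. The list means were -1.21 ± 0.61 (adjusted p = 1.72e-21 and adjusted p = 0.1001 with an estimated correlation) and -0.99 ± 0.71 (adjusted p = 6.10e-16 and adjusted p = 0.186 with an estimated correlation). CCNE2 (-2.49 ± 1.00), RRM2, a subunit of ribonucleotide reductase (-2.24 ± 1.00), the replication factor MCM10 (-2.05 ± 1.06), SPC25, a kinetochore protein (-2.02 ± 0.93), E2F8 (-1.90 ± 0.84), the mitotic kinesins KIF20A (-1.71 ± 1.11) and KIF11 (-1.58 ± 0.85) and the kinase CDK2 (-1.30 ± 0.65) were among the lowest. CDK2 stood in the list of pigment cell markers, of which 1 of 11 rose and 2 fell (adjusted p = 0.227).

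Lipid and energy metabolism genes were lower as well. Of 16 cholesterol synthesis genes 15 fell and 0 rose (INSIG1, -2.33 ± 1.02 and IDI1, -1.41 ± 0.67, list adjusted p = 4.01e-10 and adjusted p = 0.1001 with an estimated correlation). Of 9 fatty acid genes 8 fell and 1 rose (FASN, -1.34 ± 0.71 and SCD, -1.07 ± 0.78, list adjusted p = 1.33e-04 and adjusted p = 0.1001 with an estimated correlation). Glycolysis genes fell in 14 of 18 cases with 0 higher (PGAM1, -0.71 ± 0.25 and LDHA, -0.62 ± 0.34, list adjusted p = 1.90e-06 and adjusted p = 0.1001 with an estimated correlation). Oxidative phosphorylation genes fell in 18 of 26 cases and rose in 2 (ATP5MC1, -0.74 ± 0.41 and SDHA, -0.54 ± 0.33, list adjusted p = 1.59e-04 and adjusted p = 0.206 with an estimated correlation). Ribosome biogenesis genes fell in 11 of 17 cases (UTP20, -0.65 ± 0.59, list adjusted p = 0.00183 and adjusted p = 0.508 with an estimated correlation). Heat shock genes fell in 9 of 13 cases and rose in 2 (HSPE1, -0.76 ± 0.40, list adjusted p = 0.0264 and adjusted p = 0.375 with an estimated correlation). CYP1B1 stayed low (-1.73 ± 1.64) in an AHR target list with 4 of 6 genes lower (adjusted p = 0.185).

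Further lists rose by 24 h with the preset correlation, though none of them passed with an estimated one. Lysosome and autophagy genes rose in 13 of 18 cases and fell in 2, with WIPI1 (1.59 ± 1.03) and MAP1LC3B, which encodes the autophagosome protein LC3B (1.47 ± 0.60, list adjusted p = 2.35e-05 and adjusted p = 0.1001 with an estimated correlation). NRF2 targets rose in 11 of 14 cases and fell in 1 (SLC7A11, 1.95 ± 1.24 and HMOX1, 1.29 ± 1.37, list adjusted p = 0.00190 and adjusted p = 0.349 with an estimated correlation). SLC7A11 is also a member of the ATF4 list. Targets of p53 rose in 9 of 16 cases and fell in 1, among them GADD45A (2.11 ± 0.98) and the TRAIL receptor TNFRSF10B (1.18 ± 0.80, list adjusted p = 0.0249 and adjusted p = 0.375 with an estimated correlation). Which factors drove the NRF2 and p53 lists was not tested. Of 20 ribosomal protein genes 16 rose and 1 fell, by small amounts (list mean 0.09 ± 0.06 and RPL12, 0.30 ± 0.13, list adjusted p = 2.71e-05 and adjusted p = 0.137 with an estimated correlation). All 8 metal response genes were higher (MT1M, 0.72 ± 1.35 and MT1F, 0.56 ± 1.12, list adjusted p = 0.0453 and adjusted p = 0.549 with an estimated correlation). As at 6 h, cross-hybridising probe sets mean that these 8 are not separate signals. With the change of the ACTB 3 prime to 5 prime difference as covariate MT1M was 0.46 (adjusted p = 0.0513) and MT1F 0.39 (adjusted p = 0.0519), and the list did not pass (adjusted p = 0.199). Nor did the list pass without MOLT-4 and SK-MEL-2 (adjusted p = 0.0546). Both settings were added after the data were seen.

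The lists that did not pass at 24 h held genes that moved apart. ERK output had 4 genes higher and 8 lower of 21 (UPP1, 1.86 ± 1.30 and EGR1, -1.63 ± 1.71, list adjusted p = 0.366). Immediate early genes had 5 higher and 7 lower of 16 (adjusted p = 0.763). VEGFA (1.28 ± 1.04) and NDRG1 (1.01 ± 0.93) were among 7 higher and 4 lower of 18 hypoxia genes (adjusted p = 0.489). NF-kappaB targets had 9 higher and 4 lower of 18 (CXCL2, 1.05 ± 1.10, list adjusted p = 0.183). Interferon genes had 6 higher and 3 lower of 17 (IRF7, 0.66 ± 0.67, list adjusted p = 0.581). YAP targets had 1 higher and 5 lower of 18 (CCN2, -0.67 ± 1.22, list adjusted p = 0.426). The BCL2 family had 4 higher and 2 lower of 12, with the pro-apoptotic genes PMAIP1 (1.11 ± 0.86) and HRK (1.02 ± 1.00, list adjusted p = 0.520). LXR targets had 2 higher and 2 lower of 7 (SREBF1, -0.83 ± 0.60, list adjusted p = 0.489). Iron genes had 1 higher and 1 lower of 5 (FTL, 0.45 ± 0.33 and ACO1, -0.23 ± 0.37, list adjusted p = 0.763). Mean and median differed in sign for immediate early genes, LXR targets, hypoxia and the kinases.

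Of 11 kinases that sorafenib binds, 1 passed at 24 h, the collagen receptor DDR2 (0.72 ± 0.97, list adjusted p = 0.970, with a mean of 0.04 that turned negative under median centring). ARAF (-0.01 ± 0.25), KDR (-0.10 ± 0.45), PDGFRB (-0.05 ± 0.44), KIT (-0.09 ± 0.48) and FLT3 (-0.02 ± 0.21) did not pass at 24 h, and KIT passed at 6 h with 0.10 ± 0.26. RAF1 and BRAF lacked a probe set assigned to a single symbol. Epithelial markers had 5 higher and 4 lower of 9 (ESRP1, 1.02 ± 1.06, list adjusted p = 0.763). Mesenchymal markers had 1 higher and 3 lower of 11 (VIM, 0.32 ± 0.58, list adjusted p = 0.763). Haematopoietic markers had 2 higher and 1 lower of 10 (CORO1A, -0.50 ± 0.61, list adjusted p = 0.763). TXNIP, the 1 measured gene of its list, moved from -0.86 at 2 h to 0.39 ± 1.02 at 24 h, and with the ACTB covariate the 24 h change was 0.33 (adjusted p = 0.0825), close to the value without it.

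At 10000 nM and 24 h 6410 genes passed (3240 higher and 3170 lower), 779 by 0.5 or more upward and 580 downward. Median centring changed the split to 2673 higher and 4628 lower. The 3 prime minus 5 prime difference of the ACTB control probe sets, a sign of RNA quality, rose by 0.32 ± 0.49 with this dose and time (49 of 57 lines; permutation p = 1e-05, the smallest the resampling allows), while that of GAPDH changed by -0.00 ± 0.22 (p = 0.914). The array median rose as well, by 0.03 ± 0.04 at 10000 nM (40 of 57 lines) and 0.03 ± 0.03 at 5000 nM at 24 h (both adjusted p = 5e-05), and by 0.02 ± 0.03 at 10000 nM and 0.01 ± 0.02 at 5000 nM at 6 h (adjusted p = 7.71e-04 and 5e-05). These shifts are small, but they bear on the numbers of higher and lower genes, which median centring turned toward lower ones. Reference genes were not constant either: of 8, 5 fell and 2 rose, HPRT1 by -0.71 ± 0.47 and ACTB by -0.30 ± 0.22, with the same sign of the list mean under both scalings (adjusted p = 0.119). Adjusted over each list alone, the counts were the same except for NRF2 targets (12 higher and 1 lower), endoplasmic reticulum genes (13 and 1), ribosomal proteins (17 and 1), lysosome genes (14 and 2), ERK output (4 and 9), LXR targets (2 and 3) and the BCL2 family (3 and 2). With an estimated correlation 1 of the 16 lists that passed, ATF4, was kept.

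**Figure D2:**
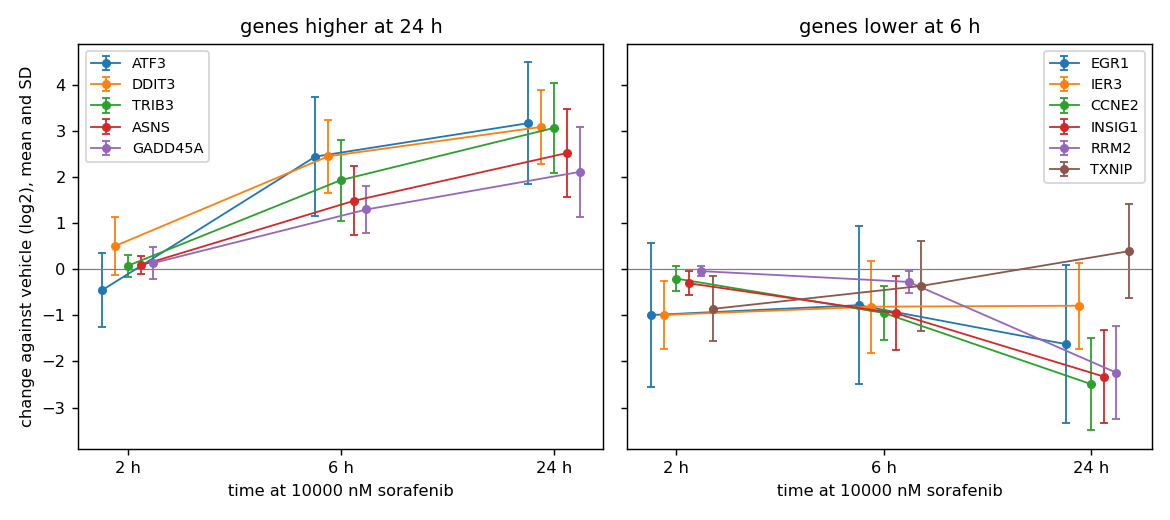
Change of 11 named genes at 10000 nM against the vehicle array of the same line (log2, y axis) at 2, 6 and 24 h; points give the mean over 59, 58 and 57 lines and bars the SD. ATF3 goes from -0.45 at 2 h to 3.17 at 24 h, and RRM2 from -0.04 to -2.24.

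The lower dose asked whether the same genes moved at 5000 nM. At 2 h rises were small, the largest being that of GADD45B (0.20 ± 0.37, n = 57). EGR1 (-0.95 ± 1.34), IER3 (-0.90 ± 0.58) and the chemokine CXCL8 (-0.85 ± 0.77) fell. At 6 h CHAC1 (1.12 ± 1.04), DDIT4 (0.97 ± 1.13) and DDIT3 (0.96 ± 0.82) rose. TXNIP (-1.07 ± 0.77), CYP1B1 (-1.06 ± 0.91) and IER3 (-0.97 ± 0.75) fell (n = 57). At 24 h TRIB3 (2.43 ± 1.05), ASNS (2.37 ± 0.96) and PCK2 (2.28 ± 0.89) were higher in 59 of 59 lines. INSIG1 (-1.57 ± 1.13), CCNE2 (-1.50 ± 1.02) and EGR1 (-1.43 ± 1.25) were lower. In limma 576 genes passed at 2 h (180 higher and 396 lower), 3047 at 6 h (1672 and 1375) and 5759 at 24 h (2882 and 2877). Median centring gave 1146 higher and 1891 lower at 6 h and 2281 and 4753 at 24 h, and the single fit of all arrays gave 97 genes at 2 h and 1789 at 6 h.

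Tested directly against 5000 nM, the largest rises at 10000 nM included those of stress genes. DDIT4 (0.80 ± 0.88), CHAC1 (0.48 ± 0.73) and DDIT3 (0.43 ± 0.48) led at 2 h (n = 57), and ATF3 (1.86 ± 0.98), CHAC1 (1.68 ± 1.22) and DDIT4 (1.62 ± 1.19) at 6 h (n = 56). At 24 h the leaders were ATF3 (1.22 ± 0.90), LAMP3 (1.18 ± 1.38) and the chaperone DNAJB9 (1.15 ± 0.72, n = 57). Lower at the higher dose were COX20 (-0.27 ± 0.28), MAFF (-0.23 ± 0.30) and KLF11 (-0.20 ± 0.27) at 2 h. At 6 h they were CCNE2 (-0.54 ± 0.57), ZFTA (-0.52 ± 0.46) and CDC25A (-0.51 ± 0.42), and at 24 h CCNE2 (-0.97 ± 0.90), the BMP target ID1 (-0.94 ± 0.87) and RRM2 (-0.90 ± 1.01). The doses differed in 213 genes at 2 h (118 higher and 95 lower), 3049 at 6 h (1375 and 1674) and 4564 at 24 h (2352 and 2212). The count at 2 h was 133 without the Lung lines and 18 in the single fit.

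The times were compared as differences between the responses to 10000 nM, since the series was designed to follow responses over time. From 2 to 6 h the response of ATF3 grew by 2.92 ± 1.46, of CHAC1 by 2.22 ± 1.20 and of DDIT3 by 1.97 ± 0.82. Those of CCNE2 (-0.75 ± 0.53), POP1 (-0.72 ± 0.41) and CDC25A (-0.71 ± 0.51) went down (n = 58). From 6 to 24 h LAMP3 (2.56 ± 2.04), NIBAN1 (2.49 ± 1.45) and the endoplasmic reticulum chaperone CLGN (1.70 ± 1.49) led the gains. RRM2 (-1.97 ± 1.07), MCM10 (-1.78 ± 1.03) and SPC25 (-1.62 ± 1.01) led the losses (n = 56). From 2 to 24 h ATF3 gained 3.66 ± 1.65, TRIB3 2.98 ± 1.02 and NIBAN1 2.98 ± 1.64. CCNE2 (-2.30 ± 1.03), RRM2 (-2.20 ± 1.03) and MCM10 (-2.08 ± 1.05) lost most (n = 57). The responses differed in 2932 genes between 2 and 6 h (1432 higher and 1500 lower at the later time), in 5219 between 6 and 24 h (2791 and 2428) and in 5736 between 2 and 24 h (2967 and 2769; 2506 and 3726 with median centring).

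Vehicle arrays changed with time too, which gives the background for these values. Against 2 h, the vehicle arrays at 6 h had more ZNF322 (0.61 ± 0.36), CLK1 (0.56 ± 0.40) and DDIT4 (0.51 ± 0.58). They had less ATF3 (-0.83 ± 1.07), KLF11 (-0.74 ± 0.42) and PMS1 (-0.65 ± 0.28; n = 59). At 24 h DDIT4 (1.33 ± 1.13), FAM200C (1.15 ± 0.48) and ZNF322 (0.97 ± 0.43) were higher. CCN2 (-1.18 ± 0.82), ATF3 (-1.18 ± 1.38) and MAFF (-1.10 ± 1.06) were lower. In limma 3483 genes differed at 6 h (1860 higher and 1623 lower) and 4269 at 24 h (2476 and 1793; 1634 and 4307 with median centring), but 15 and 98 by 0.5 or more.

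Tissue of origin was compared to see which lines responded differently to 10000 nM at 6 h. The 6 Leukemia lines stood apart: in limma 976 genes differed from the other tissues (372 higher and 604 lower), and 582 without MOLT-4 and CCRF-CEM. The histone gene H2AC6 rose by 3.79 ± 1.45 in them (3.12 above the other tissues), JUN by 2.74 ± 1.49 (1.92 above) and MT1G by 2.54 ± 1.85 (1.85 above, and 1.35 with adjusted p = 0.0647 without MOLT-4 and SK-MEL-2). The iron transporter SLC11A2 (-1.16 ± 0.67), the glycosyltransferase B4GALT5 (-1.44 ± 0.57) and SOX4 (-0.53 ± 1.26) had lower mean changes in Leukemia than in the other tissues, by -1.23, -1.22 and -1.14. Of these B4GALT5 had a mean below 0 in every other tissue, while that of SOX4 was above 0 in each of them. The F test over 8 tissues called 354 genes (209 without MOLT-4 and HCT-116), and 158 without MOLT-4 and CCRF-CEM, led by TWF1 (Leukemia mean -1.01 ± 0.23), PON2 (-0.72 ± 0.21), IRAG2 (0.90 ± 0.17), NCKAP1 (-0.89 ± 0.30) and the glucosidase MOGS (-1.20 ± 0.19).

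Few genes set the other tissues apart at 6 h. The 7 Colon lines differed in 22 genes (15 higher and 7 lower), with higher changes of SLC1A4 (0.77 above the rest, and 0.67 with adjusted p = 0.0797 without MOLT-4 and HCT-116), the splicing regulator ESRP1 (0.70) and CLIC4 (0.67). Lower changes were those of DUSP2 (-1.15), HS3ST1 (-0.88) and GPRC5A (-0.67). The 6 CNS lines differed in 5 genes, with TCIM (1.39), DDR2 (0.99) and FAM110B (0.87) higher and CCNG1 (-0.42) lower. Without SNB-19 and NCI-ADR-RES TCIM was 0.86 (adjusted p = 0.187) and CCNG1 -0.40 (adjusted p = 0.0634). Renal lines had 4 higher genes, including CLTCL1 (0.67), OXR1 (0.60) and ANKRD28 (0.45). Of Renal genes 0 passed after quantile normalization, against all other lines pooled, without SNB-19 and NCI-ADR-RES, or without MOLT-4 and CCRF-CEM, though without SNB-19 and NCI-ADR-RES the differences stayed at 0.66, 0.59 and 0.45. LOX, a collagen crosslinking enzyme, was the 1 gene of the Ovarian lines (0.75). In limma 0 genes passed in the Breast, Lung and Melanoma contrasts, with 940, 591 and 817 at an unadjusted p under 0.05. Leaving out 1 Breast line gave 2 to 13 genes for Breast (2 without MCF7, 3 without T-47D, 9 without HS-578T, 11 without BT-549 and 13 without MDA-MB-231). Leaving out SK-MEL-5, whose 6 h response ran opposite to the other lines, gave 18 genes for Melanoma, and leaving out MOLT-4 and SK-MEL-2 gave 13. Every tissue setting without MOLT-4, HCT-116, SK-MEL-2, SK-MEL-5, or the pairs with CCRF-CEM and SNB-19, was added after the data were seen.

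At 24 h tissues differed in 1110 genes by the F test, led by CD37 and LAIR1, both leukocyte surface proteins (Leukemia means 1.36 ± 0.95 and 1.38 ± 0.72), LAPTM4B (-1.63 ± 0.92), RSAD1 and, in Colon, SLC12A2 (-2.24 ± 0.54). Leukemia, with 4 arrays, differed in 548 genes (235 higher and 313 lower; 270 without CCRF-CEM, and 210 without MOLT-4 and CCRF-CEM, which leaves 2 lines). The array labelled MOLT-4 at 10000 nM and 24 h resembled CCRF-CEM, lying 0.812 of the way from MOLT-4 to that line. It and the vehicle array of CCRF-CEM at 24 h were each other's best match (r = 0.990), so both arrays are in doubt. TM6SF1 was 2.04 above the other tissues, MT1E 2.17 (0.87 without K-562, adjusted p = 0.288) and HPGD 2.20 (1.00 without MOLT-4, adjusted p = 0.192). LARP6 (-2.11), GADD45A (-1.99) and CBS (-1.88; -1.75 without CCRF-CEM, -1.71 without MOLT-4 and -1.89 without K-562, adjusted p = 0.167, 0.136 and 0.0903) lay lower. Without MOLT-4 and CCRF-CEM LARP6 (-2.20) and GADD45A (-1.67) missed the threshold too (adjusted p = 0.0784 and 0.149).

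The 7 Colon lines differed in 309 genes at 24 h (197 higher and 112 lower; 171 without MOLT-4 and HCT-116). DDIT4 (2.23), the selenium transport gene SELENOP (2.15) and NEBL (1.77) were higher there than in the other tissues, and the stem cell receptor LGR5 (-1.66), BMP4 (-1.60) and MYB (-1.52) lower. The 8 Melanoma lines differed in 283 genes (97 higher and 186 lower), and in 429 without MOLT-4 and SK-MEL-2. All 9 arrays labelled SK-MEL-2 resembled the colon line HCT-116 (r = 0.966 between the vehicle profiles) and had little pigment gene expression (list level 4.94, against a median of 10.25 in the other 7 Melanoma lines), as had the Melanoma line LOX (5.04), so that level alone does not set them apart. Their epithelial list level does (10.11, against at most 5.83 in the other Melanoma lines). In Melanoma CCN1 (1.50) and DDR2 (1.49) were higher and MAFF (-2.08) and LPXN (-1.86) lower. ID3 was higher (1.37) and GDF15 lower (-2.25). Without SK-MEL-5 these differences stayed about as large (1.25 and -1.94) with 1 line fewer, while their adjusted p rose to 0.0974 and 0.0707. The ERK list fell in 8 of 8 Melanoma lines (-0.86 ± 0.51) and averaged 0.02 ± 0.69 in the other 49 lines (difference -0.87, permutation p = 0.00102). It also fell in 23 of those 49 lines, and the lowest of all lines was the Breast line MDA-MB-231 (-1.70). The permutation p was not adjusted over the lists, tissues and times that could be compared.

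**Figure D3:**
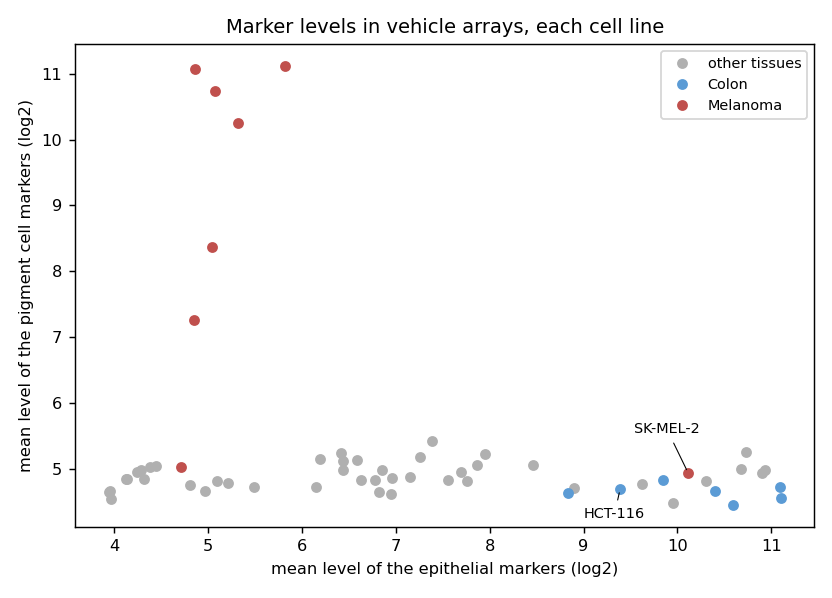
Mean level of the epithelial marker list (log2, x axis) against that of the pigment cell marker list (log2, y axis) in the vehicle arrays of each cell line (points), with Colon and Melanoma lines in colour. SK-MEL-2 lies at 10.11 and 4.94, near HCT-116 at 9.39 and 4.70.

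**Figure D4:**
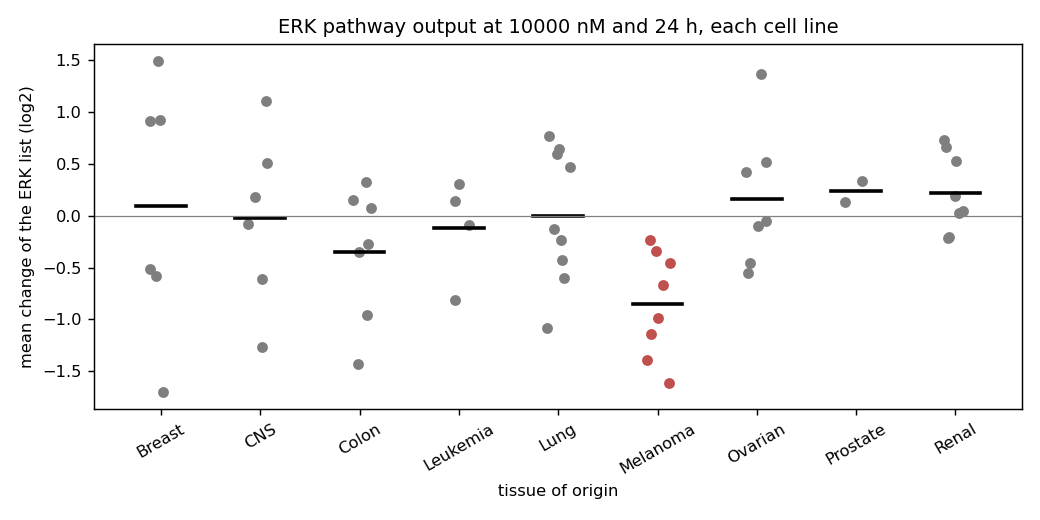
Mean change of the ERK pathway output list (log2, y axis) at 10000 nM and 24 h in each cell line (points), by tissue of origin; horizontal marks give the tissue mean. The 8 Melanoma lines lie between -1.62 and -0.24, and the other tissue means lie between -0.35 and 0.24.

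The 6 CNS lines differed in 190 genes (113 higher and 77 lower), in 91 against all other lines pooled, and in 63 without SNB-19 and NCI-ADR-RES. SNB-19 counts as CNS and its vehicle profile correlated at 0.935 with that of U251, another CNS line. The glycoprotein gene GPNMB (2.33), ECM2 (1.93) and CPEB1 (1.76) were higher than in the other tissues. The chemokine CCL2 (-2.29), TMT1A (-1.92) and CCN1 (-1.82) were lower. Without SNB-19 and NCI-ADR-RES TMT1A was -1.51 (adjusted p = 0.211), while ECM2 (1.97, adjusted p = 0.1007) and CCL2 (-2.18, adjusted p = 0.0696) kept their size and missed the threshold, and both also missed it against all other lines pooled (adjusted p = 0.0777 and 0.0615). The 6 Breast lines differed in 45 genes (15 higher and 30 lower; 27 after quantile normalization), among them MAP2 (1.86), PEG10 (1.68), PRSS23 (1.33), NRP1 (-1.61), CAMK2N1 (-1.39) and LTBP1 (-1.26). Without MOLT-4 and SK-MEL-2, which are not Breast lines, NRP1 (-1.61) and LTBP1 (-1.26) did not move and their adjusted p rose to 0.0519. The count was 23 against all other lines pooled and 23 without SNB-19 and NCI-ADR-RES. The 8 Renal lines differed in 28 genes (12 higher and 16 lower), with SNAI2 (1.48), NRCAM (1.09) and LAT (1.08) higher. The kidney injury gene HAVCR1 (-1.79), KCNJ16 (-1.77) and ZBED2 (-1.33) were lower. ZBED2 was -1.34 without MOLT-4 and SK-MEL-2 (adjusted p = 0.0545). The 7 Ovarian lines differed in 12 genes (7 without MOLT-4 and SK-MEL-2). BAMBI (1.70), TNC (1.67) and MOCOS (1.62) were higher and MEOX1, CP (-0.76) and RBMS2 (-0.73) lower. Without MOLT-4 and SK-MEL-2 the differences of TNC (1.68), MEOX1 (-1.02), CP (-0.76) and RBMS2 (-0.73) hardly moved while their adjusted p rose to 0.0612, 0.0529, 0.0529 and 0.0612. Without SNB-19 and NCI-ADR-RES, of which the latter counts as Ovarian, TNC was 1.24 (adjusted p = 0.294), MOCOS 1.41 (adjusted p = 0.0717) and RBMS2 -0.55 (adjusted p = 0.280). The count was 7 against all other lines pooled and 2 without MOLT-4 and CCRF-CEM. The 9 Lung lines differed in 4 genes, LGSN (1.07), EGFR (0.74), RRAS2 (0.62) and CNPY4 (-0.35). Against all other lines pooled LGSN alone passed, and EGFR (0.71), RRAS2 (0.58) and CNPY4 (-0.34) did not (adjusted p = 0.126, 0.256 and 0.124). Of genes with higher signal, 2 passed for Lung, EGFR and RRAS2. Of 66 tissue differences of named genes 20 missed the threshold against all other lines pooled, and 20 missed it without MOLT-4 and CCRF-CEM.

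The number of changed genes differed widely between lines. Each number rests on 1 treated and 1 vehicle array, so a line's response cannot be told from a deviating array. The median number of genes moved by at least 1 (log2) was 18, 106.5 and 768 at 10000 nM and 11, 29 and 303 at 5000 nM (2, 6 and 24 h). At 10000 nM and 24 h it ran from 217 in the renal line RXF-393 to 1570 in the lung line NCI-H226. Within lines the higher dose moved 8.91 more genes at 2 h (SD 35.8, permutation p = 0.0289, but p = 0.0596 for genes moved by at least 0.5), 92.3 at 6 h (SD 95.1) and 426 at 24 h (SD 223, higher in 57 of 57 lines; both p = 1e-05, the smallest the resampling allows).

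Of 5 relations tested across lines at 10000 nM, 2 held in every form tried and 1 in part. Lines with more ERK output loss at 2 h also had more at 6 h (n = 58, r = 0.597, adjusted permutation p = 2.5e-05; rho = 0.548, adjusted p = 5e-05; r = 0.534 without EKVX and HS-578T; r = 0.551 within tissues). Taken tissue by tissue, without a test, r for the ERK lists ran from 0.050 in the 7 Colon lines to 0.806 in the 8 Renal lines. The cholesterol list at 6 h followed that at 24 h (n = 56, r = 0.625, p = 1e-05, adjusted p = 2.5e-05; rho = 0.632, adjusted p = 5e-05; r = 0.642 without MOLT-4 and SK-MEL-5; r = 0.608 within tissues). The ATF4 list at 6 h was related to that at 24 h (n = 56, r = 0.456, p = 0.00057, adjusted p = 0.00095; rho = 0.335, adjusted p = 0.0192; r = 0.481 within tissues), and r was 0.302 (p = 0.0262) without MALME-3M and SK-MEL-5. With list medians in place of means it did not hold in every form (r = 0.372, adjusted p = 0.00885; rho = 0.224, adjusted p = 0.161), and r was 0.202 (p = 0.142) without the same lines. The fall of the mitosis list at 24 h was not detectably related to the ERK list at 6 h (r = -0.204, p = 0.131; rho = -0.164, p = 0.227) or to the ATF4 list at 6 h (r = -0.260, p = 0.0540; rho = -0.235, p = 0.0812).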

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

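The tests of the SK-MEL-2 and SK-MEL-5 arrays, the position of the MOLT-4 and HCT-116 arrays between lines, and the settings without these lines, CCRF-CEM, or (for tissues) SNB-19 and NCI-ADR-RES were chosen only after the results were seen.

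Of 524 arrays 3 matched another line best: MOLT-4 at 10000 nM and 24 h, the CCRF-CEM vehicle at 24 h and HCT-116 at 10000 nM and 24 h. The array labelled MOLT-4 at 10000 nM and 24 h lay 0.812 of the way (quartiles 0.617 and 0.897) from MOLT-4 to CCRF-CEM over 87 genes that separate these lines. A drug response is argued against by the MOLT-4 array at 5000 nM and 24 h, which lay at -0.0013. A wrong or mixed array may account for it, with an estimated 73.4 to 85.4% of CCRF-CEM signal. The CCRF-CEM vehicle array at 24 h was its best match (r = 0.990, both ways) and lay at 0.891 where the other CCRF-CEM arrays lay between 0.980 and 1.07, so it is in doubt as well, for a reason that was not tested. All 9 arrays labelled SK-MEL-2 resembled HCT-116: the vehicle profiles correlated at 0.966, as high as those of NCI-ADR-RES and OVCAR-8 (0.966), and 0.304 above the highest r with another melanoma line, so RNA of a line close to HCT-116 is a candidate explanation. A melanoma line that only lost its pigment genes is argued against, since the epithelial list lay 4.29 above the highest other melanoma line (EPCAM, 11.97 in SK-MEL-2, 11.84 in HCT-116 and 3.61 in other melanoma lines). Yet VIM (10.12 against 5.68 in HCT-116) and SPARC (8.12 against 3.67) show that the profiles are not the same. Of 17 genes at least 3 apart between these lines in vehicle at 2 and 6 h, all were higher in SK-MEL-2. Whether the SK-MEL-2 arrays hold a mixture of RNA was not tested. For the array labelled HCT-116 at 10000 nM and 24 h, whose best match was SK-MEL-2, positions of 0.217 there and 0.106 at 5000 nM over 17 genes leave a mixed array and a drug response both open.

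SK-MEL-5 stood apart from the other melanoma lines at 10000 nM: its ATF4 list changed by -0.51 at 6 h and by 0.041 at 24 h, and its cholesterol list by 0.426 at 6 h. At 6 h its change correlated at -0.312 with the mean of the other lines, and its vehicle array followed the drug response of the others by 0.293 more (r) than its 10000 nM array did, in 1 of 58 lines, so an exchange of these 2 arrays may account for 6 h. The 5000 nM response at 6 h rests on the same vehicle array. There its ATF4 list changed by -0.175 (lowest other line -0.166), and r with the mean of the other lines was -0.078. A line without the response is argued against by the rise of the ATF4 list by 1.27 at 5000 nM and 24 h. At 24 h 658 genes differed from vehicle by at least 1 and the ERK list by -0.99, which met a prediction against an untreated array written after the data were seen. The count alone does not show a drug response, so an untreated array is not excluded. The doubted MOLT-4 array gave 600 such genes with an r of 0.1135 to the mean of the other lines. What sets the SK-MEL-5 array apart at 24 h stays open, and no biological explanation was tested. Earlier forms of both tests were run and replaced: the vehicle list levels of 8.27, 8.62 and 8.33 (2, 6 and 24 h) left the exchange undecided, and the lower r at 10000 nM than at 5000 nM and 24 h (0.0971 against 0.520) met the prediction of a missing dose.

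The ERK list fell more in melanoma lines at 24 h than in other lines (difference -0.87, 95% interval -1.39 to -0.36), but not detectably at 2 h (0.05, permutation p = 0.719) or 6 h (-0.21, permutation p = 0.318). Neither the interval nor the permutation p was adjusted for the choice of list, tissue and time. The doubted arrays are argued against, since the difference was -0.96 without SK-MEL-2, SK-MEL-5, MOLT-4 and HCT-116, though CCRF-CEM was kept. It was -0.86 with the ACTB difference as covariate, which met the prediction against RNA quality. That holds only as far as the ACTB difference reads RNA quality. The GAPDH difference did not change (-0.00 ± 0.22) and the ACTB transcript itself fell, so RNA quality is not excluded. With the vehicle level of the list as covariate (8.44 in melanoma against 7.62 in other lines) the melanoma difference was -0.68 with an upper bound of -0.16, so a higher starting level stays open as part of the cause. A lasting dependence of these genes on RAF signalling in melanoma lines is a hypothesis of tissue biology that remains untested, since no genotype was used.

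Of 80 groups examined for a line far from the rest 7 held one, where chance gives about 1 in 20. Besides the SK-MEL-5 values, the ATF4 list of SR was the lowest of the Leukemia lines at 6 h (0.864), and the mitosis list of EKVX the lowest of the Lung lines (-0.593). The numbers of genes changed by at least 1 were highest in COLO-205 among Colon lines (535) and in 1 line among the Renal ones (508) at 6 h, and in NCI-H226 among Lung lines at 24 h (1570).

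The response to 10000 nM differed between times in 2932 genes (2 and 6 h), 5219 (6 and 24 h) and 5736 (2 and 24 h), each by its own test. In 100 exchanges of arrays within lines the real arrangement alone, 1 of 100, gave as many, and the highest other gave 1, 1333 and 85 genes. The same holds for the counts of all other comparisons within lines: 576, 1219, 3047, 4259, 5759 and 6410 against vehicle, 213, 3049 and 4564 between doses and 3483 and 4269 between vehicle times, where the highest other arrangement gave 8 genes. All met the share of under 0.05 set beforehand, which argues against chance alone. That share, 1 of 100, is the smallest these draws allow and was not adjusted over comparisons. Close pairs of lines were exchanged as if independent, and the size of the counts was not tested.

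Tissues differed at 6 h in 354 genes by the F test and in 976 for Leukemia, 22 for Colon, 5 for CNS, 4 for Renal and 1 for Ovarian. At 24 h they differed in 1110 genes by the F test and in 548 for Leukemia, 309 for Colon, 283 for Melanoma, 190 for CNS, 45 for Breast, 28 for Renal, 12 for Ovarian and 4 for Lung. With tissue labels permuted, 1 of 100 arrangements, the real one, gave as many genes for both F tests (highest other 2), for Leukemia (36 at 6 h and 67 at 24 h), Colon (14 and 6) and Renal (1 and 2) at both times, and for Breast (23), CNS (9) and Melanoma (44) at 24 h. These counts met the share of under 0.05 set beforehand, without adjustment over tissues. The permutation treats lines as exchangeable, yet SNB-19 and U251, NCI-ADR-RES and OVCAR-8, and MOLT-4 and CCRF-CEM are close pairs within a tissue. Shuffled labels tend to split them, so the test does not separate a tissue difference from the likeness of such pairs. Without SNB-19 and NCI-ADR-RES the CNS count at 24 h was 63, and without MOLT-4 and CCRF-CEM the Leukemia count was 210. The 4 Renal genes at 6 h are weak evidence all the same, since 0 passed in 4 other settings. For Lung (highest other 20) and Ovarian (67) at 24 h 3 of 100 did, which meets that share but not by much, so the evidence against chance is weak there. At 6 h 5 of 100 arrangements reached the CNS count (highest other 77) and 18 the Ovarian count (25), so chance is not excluded there. For Breast, Lung and Melanoma at 6 h the real count was 0, which all 100 arrangements reach by construction (highest other 356, 25 and 5), so the test decides nothing for them. Arrangements with several times the real count point to some structure among the lines, and what it is was not tested.

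Probe sets without a single gene symbol also responded: of 3151, 1346 passed at 10000 nM and 24 h (654 higher and 692 lower), and they were not named.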

How the results depend on the processing

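The settings without MOLT-4, HCT-116, SK-MEL-2, SK-MEL-5 or CCRF-CEM, that without SNB-19 and NCI-ADR-RES for tissues, and the ACTB covariate were chosen only after the data were seen. Counts against vehicle at 10000 nM lay within 1.5 times the reported ones in most settings (980 to 1462 at 2 h, 3278 to 4516 at 6 h and 4511 to 7579 at 24 h). Apart from the missing block and the stricter threshold, where the construction gives the reason, the cause of the changes below was not tested. Without the replicate block, treating arrays as unpaired, counts fell to 0, 2, 4, 253, 1447 and 2891 for 5000 and 10000 nM at 2, 6 and 24 h, 0, 29 and 195 for dose, 36, 881 and 1470 for time, and 22 and 235 for vehicle; the construction shows why, since differences between lines then count as noise. One fit of all arrays gave 97 (5000 nM) and 367 (10000 nM) at 2 h, 1789 (5000 nM, 6 h) and 18 (dose, 2 h); for the vehicle comparisons it could not be estimated. At an adjusted p of 0.01 counts were 346, 733 and 104 for 5000 nM, 10000 nM and dose at 2 h, and the dose count at 2 h was 133 without the Lung lines. Median shifts of all genes under other scalings stayed under 0.1.

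For tissues at 6 h, leaving out MOLT-4 and HCT-116 gave 209 genes by the F test and 5 for Breast; leaving out MOLT-4 and SK-MEL-2 gave 4 for Breast and 13 for Melanoma, and leaving out SK-MEL-5 gave 3 and 18. Leaving out 1 Breast line gave 2 to 13. Renal had 0 after quantile normalization and 0 against all other lines pooled. With only genes of higher signal CNS had 1 and Colon 14 at 6 h, and Breast 12, Lung 2, Melanoma 171, Ovarian 6 and Renal 12 at 24 h. At 24 h quantile normalization gave 27 for Breast; without MOLT-4 and HCT-116 Colon had 171 and Ovarian 7; without MOLT-4 and SK-MEL-2 Melanoma had 429 and Ovarian 7; leaving out 1 Leukemia line gave 270 to 520 (270 without CCRF-CEM). Leaving out SNB-19 and NCI-ADR-RES gave 0 for Renal at 6 h and 23 for Breast and 63 for CNS at 24 h. Leaving out MOLT-4 and CCRF-CEM gave 158 by the F test, 582 for Leukemia, 4 for Breast and 0 for Renal at 6 h, and 210 for Leukemia, 1 for Lung and 2 for Ovarian at 24 h. Pooling all other lines gave 23 for Breast, 91 for CNS, 1 for Lung and 7 for Ovarian.

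Lists past the threshold numbered 8, 3 and 1 at 2, 6 and 24 h with an estimated correlation (14, 11 and 16 with the preset one), and 17 and 26 with fry at 6 and 24 h. Without MOLT-4 and HCT-116 the lists of ATF4 (camera, adjusted p = 0.0593), NRF2 targets (0.0585) and the BCL2 family (0.0642) missed the threshold at 2 h. At a difference of 0.5 the doses moved 71.5 more genes per line at 2 h (permutation p = 0.0596). RAB27A, lower at 24 h on its brightest probe set, was 0.05 (0.0474) as a mean of probe sets, 0.34 without probe sets marked as cross-hybridising and 0.35 on its most variable one, where LPCAT3 was 0.44. Of the other gene values 7776 kept their side and sign, 386 were no longer past the threshold and 14 became so. Signal near background limits genes below the median mean level of 5.98, and an absolute level was not measured.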

Other observations

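Gene families defined by their names were chosen and tested only after the data were seen (13 families at 3 times, 39 tests adjusted together, 10000 nM against vehicle). None passed with an estimated correlation. They are not independent of the fixed lists: the amino acid transporters include SLC3A2, SLC7A11, SLC7A5 and SLC7A1 of the ATF4 list, so that result partly repeats it, and some members of other families are in the lists of lysosome, ribosome biogenesis, heat shock and reference genes.

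At 24 h (n = 57 lines) all 6 measured genes of antigen presentation by HLA class I, B2M included, were higher, with a mean of 0.40: HLA-B by 0.61 ± 0.34 in 57 of 57 lines and HLA-C by 0.54 ± 0.38 (adjusted p = 0.00134 and adjusted p = 0.245 with an estimated correlation). Whether the probe sets of the HLA genes share a signal was not tested, so these may not be 6 separate rises. Of 33 proteasome subunits 21 fell and 5 rose (adjusted p = 2.04e-04 and adjusted p = 0.250 with an estimated correlation). PSMD1 fell by -0.53 ± 0.25 and PSMB3 by -0.48 ± 0.22, while PSMB9, a subunit of the immunoproteasome, rose by 0.80 ± 0.82. Amino acid transporters rose in 14 of 27 cases and fell in 3, with SLC3A2 at 1.85 ± 0.65 in 57 of 57 lines and SLC1A4 at 1.47 ± 0.96 (adjusted p = 0.0197 and adjusted p = 0.245 with an estimated correlation). Tubulins fell in 9 of 16 cases and rose in 3 (TUBB4B, -0.82 ± 0.36, TUBG1, -0.74 ± 0.40 and TUBB2B, 0.83 ± 1.18, adjusted p = 0.0154 and adjusted p = 0.345 with an estimated correlation). Mitochondrial ribosomal proteins fell in 28 of 48 cases and rose in 9 (MRPS28, -0.64 ± 0.28, adjusted p = 0.00536 and adjusted p = 0.599 with an estimated correlation), and 110 of 250 zinc finger genes rose against 38 that fell (ZNF623, 0.87 ± 0.51, adjusted p = 0.00536 and adjusted p = 0.245 with an estimated correlation). The list means kept their sign under median centring and quantile normalization.

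At 6 h (n = 58 lines) all 4 CDC-like splicing kinases rose, with a family mean of 0.22 (adjusted p = 0.00775 and adjusted p = 0.245 with an estimated correlation), and 14 of 42 histone genes rose and 0 fell (mean 0.15, adjusted p = 0.00536 and adjusted p = 0.650 with an estimated correlation). At 24 h 5 histone genes were higher and 14 lower (mean -0.02, adjusted p = 0.465). RNA polymerase I and III subunits fell in 8 of 13 cases and rose in 2 (adjusted p = 0.00775 and adjusted p = 0.335 with an estimated correlation). Proteasome subunits (12 of 33 fell and 2 rose, adjusted p = 0.0381), amino acid transporters (10 of 27 rose and 4 fell, adjusted p = 0.0413) and tubulins (9 of 16 fell and 1 rose, adjusted p = 0.00971) already passed at 6 h. With an estimated correlation their adjusted p was 0.573, 0.245 and 0.345. At 2 h (n = 59 lines) 2 of 4 CDC-like kinases rose (adjusted p = 0.00203 and adjusted p = 0.101 with an estimated correlation). These means kept their sign under both scalings. V-ATPase subunits, tetraspanins, serpins and cathepsins did not pass at any of the 3 times (lowest adjusted p = 0.116).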
